A study of Homo sapiens with 12 samples.

How the data were processed

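The series holds RNA-seq of the human melanoma lines A2058, A375 and SKMEL-5, each in normoxia and in 1% oxygen, with 2 libraries per line and condition (12 libraries in 6 groups). Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made from total RNA with a NuGen Universal Plus mRNA kit. The submitters' processing notes name bcl2fastq 2.20, Trim Galore 0.6.1, STAR 2.5.0a and the GRCh38 build. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could have been assigned in more than 1 way.

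The authors deposited 1 table of raw counts per gene for all 12 libraries, with no normalization. It lists 60656 versioned Ensembl gene IDs, 23267 of them with no count in any library, and its 12 value columns carry the sample titles, so that each column was matched to its sample by name. Symbols came from a reference table of gene names, which matched 60445 IDs with the version ignored and 51592 with the same version. Gene types and positions came from GENCODE 29 on GRCh38, which placed 58438 IDs. Where IDs shared a symbol (1239 IDs), the symbol went to the ID with the most counts. Library totals ran from 33831569 to 54202819 counts. The limit that a count of 0 allows, 3 counts of the total, was 0.0553 to 0.0887 CPM and covers counting error only.

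Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 6 groups (minimum count 10, minimum total count 15), which left 19636, and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries together, so that the groups shared an estimate of the spread with 6 residual degrees of freedom, 5.02 prior degrees of freedom and a common biological coefficient of variation of 0.453. The contrasts were hypoxia minus normoxia within each line, the mean of these 3 differences, and an F test of whether the 3 differences were equal. p-values were adjusted by Benjamini-Hochberg over the tested genes, and an adjusted p under 0.05 was called. Every adjusted p of a gene is from edgeR unless another tool is named. Standard errors are the absolute log2 change divided by the square root of the F statistic of its test. CPM values of single genes are TMM-scaled, except those of line markers, which are CPM of the library total; log2 CPM used a prior count of 2.

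Before the data were examined, 28 gene lists were written down: hypoxia response, glycolysis and glucose transport, TCA cycle, nuclear-encoded and mitochondrially encoded respiratory chain, sterol synthesis and uptake, unfolded protein and amino acid stress response, proliferation, collagen and matrix, melanocytic genes, dedifferentiated and invasive melanoma, interferon response, class I antigen presentation, 12 lists on sugars (N-glycan processing, poly-LacNAc extension, sialyltransferases, sialic acid metabolism, fucosylation, O-GalNAc glycosylation, glycosaminoglycan synthesis, proteoglycan core proteins, glycosphingolipids, galectins, hexosamine and nucleotide sugars, the dolichol pathway), and markers of fibroblasts, keratinocytes and blood cells. Of their 552 members 551 matched an ID. Lists were tested in the 3-line mean with limma 3.58.1's camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. List medians are over the members with at least 1 count in every group.

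The rule for the genes named in the text was also fixed before the data were examined. It took the 10 largest rises and 10 largest falls among called protein-coding genes of the 3-line mean that moved the same way in each line and had at least 2 CPM, the 6 largest called rises and falls of each line, the 10 genes of at least 10 CPM with the smallest p for a difference between lines, and up to 2 called members per direction of each list (4 for the sugar lists), or the member with the smallest p where none was called. CA9, VEGFA, GCNT2, LGALS1, LGALS3, LGALS8, ST6GAL1, ST3GAL1, MGAT5, FUT8, MITF, AXL, HIF1A, EPAS1 and ARNT were named whatever their values. It gave 73 genes, of which 35 were called in the 3-line mean. Other genes named to spell out a small count, and those of a later part on demethylases, IGF-binding proteins and lipid genes, were chosen after their values were seen.

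The procedure was tested on simulated counts with the observed means, spread and library sizes, drawn independently for each gene and library. There were 200 changed genes, and the members of the sterol list were also raised 2-fold. The shares of the 200 recovered are given with the results. Replicates were compared by the median over genes of a chi-square statistic of their counts. Alternatives fixed before the data were examined were DESeq2's size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter at 1 CPM in 2 libraries, a replicate block within each line, a minimum absolute log2 change of 1, an additive model, the libraries of 1 line alone and each library left out in turn. Alternatives added after the data were seen were to leave out the 3 hypoxic libraries that stood apart, a replicate block shared by the lines or crossed in A2058, means of 2 lines, regroupings that moved A375 and SKMEL-5 libraries together, removal of a transcript length trend, and leaving out mitochondrial genes. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.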

Results

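RNA was sequenced from 3 established human melanoma cell lines, A2058, A375 and SKMEL-5, which the labels describe as metastatic. Each line was grown in atmospheric oxygen (normoxia, the reference) and in 1% oxygen (hypoxia). There were 2 libraries per line and condition, called biological duplicates in the series' design text, so that 12 libraries fell into 6 groups of 2. The series' title sets the question: what low oxygen does to the genes that build and bind sugar chains in melanoma cells. The deposited counts summed to 39798648 and 33831569 in A2058 normoxia and 44522900 and 41766281 in A2058 hypoxia (replicates 1 and 2 here and below). The sums were 50999425 and 40437506 in A375 normoxia and 42176286 and 43784449 in A375 hypoxia. In SKMEL-5 they were 41450962 and 47924592 in normoxia and 43212823 and 54202819 in hypoxia. Between 15890 and 18072 genes had at least 10 counts in a library, and 3 counts, the limit that a count of 0 allows, corresponded to 0.0553 to 0.0887 CPM (counts scaled to the library total). These limits cover counting error only.

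The melanocyte genes TYR and MLANA, which encode a pigment enzyme and a melanosome antigen, averaged 94.5 ± 62.9 and 21.9 ± 13.2 CPM (SD, n = 4) in A2058 and had 0 counts in the A375 and SKMEL-5 libraries, while the neural crest factor SOX10 averaged 1099, 1032 and 942 CPM in A2058, A375 and SKMEL-5. Between A375 and SKMEL-5 libraries, Pearson's r of log2 CPM across the 19636 tested genes was 0.912 to 0.990, which overlapped the range within A375 (0.917 to 0.982), and genes are not independent replicates. A2058 libraries correlated with those of the other lines at 0.810 to 0.880. Averaged over both oxygen conditions, 2 genes differed between A375 and SKMEL-5 in edgeR's quasi-likelihood test, TSSC2 and DLGAP1, against 5418 between A2058 and A375 and 5260 between A2058 and SKMEL-5. Of the 8 A375 and SKMEL-5 libraries, 7 correlated best with the library of the other name that had the same culture condition and replicate number. TSSC2 and DLGAP1 were picked after their values were seen.

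**Figure D1:**
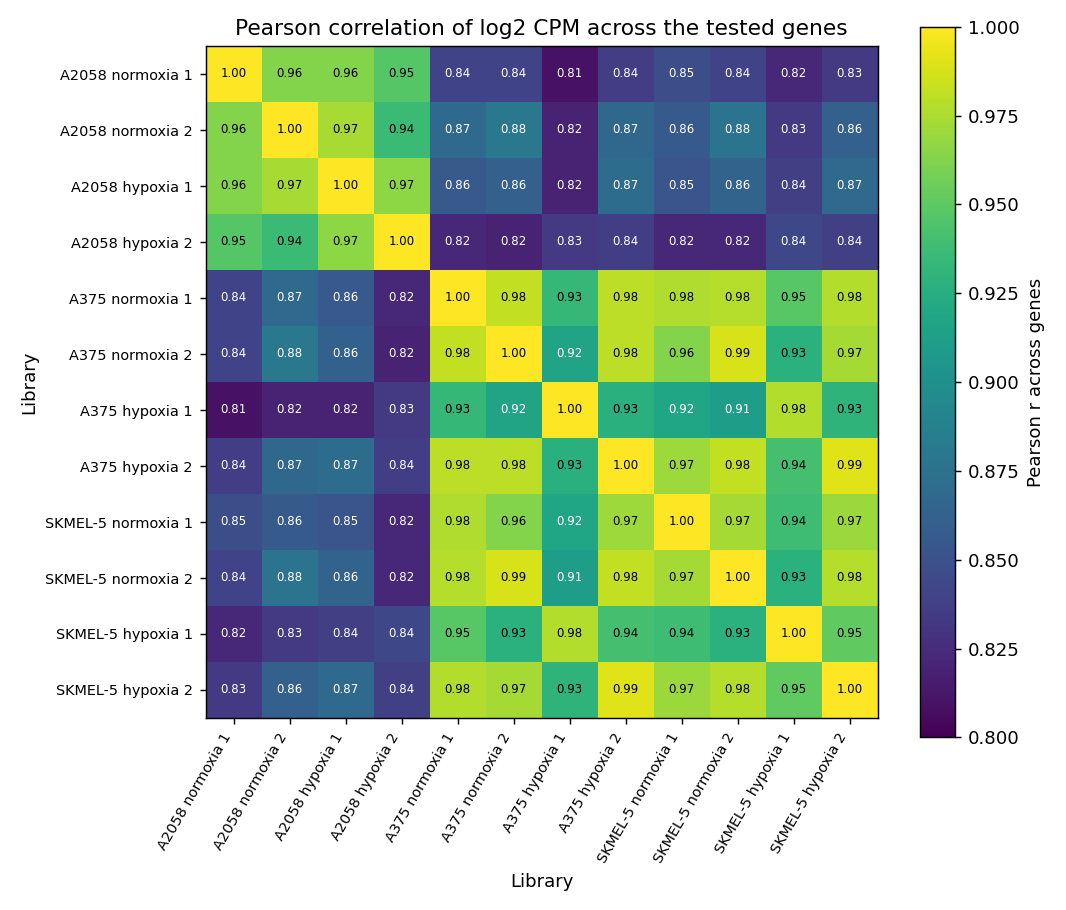
Pearson's r of log2 CPM across the tested genes for each pair of the 12 libraries, on both axes ordered by line, oxygen condition and replicate. A375 and SKMEL-5 libraries correlate with each other at 0.912 to 0.990, and with A2058 libraries at 0.810 to 0.880.

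Replicates differed by more than counting noise in every group, with a median chi-square per gene from 12.5 (A375 normoxia) to 63.2 (A375 hypoxia), so no pair held the same library deposited again. In each line 1 hypoxic library stood apart: A2058 hypoxia 2, A375 hypoxia 1 and SKMEL-5 hypoxia 1. On the principal component that held 47.1% of the variance within lines, these 3 libraries scored 72.7, 132 and 108, and every other library scored below 0. Compared with the other hypoxic library of the line, the clock output gene DBP was higher by 3.28, 5.56 and 3.52 on the log2 scale in A2058, A375 and SKMEL-5, and the mitochondrial ribosomal RNA MT-RNR2 by 1.32, 5.28 and 3.50. In all 3, 729 genes were at least 2-fold higher and 972 at least 2-fold lower than in the other hypoxic library. The normoxic libraries also differed: CA9 stood at 19.0, 4.91 and 9.81 CPM in normoxia replicate 1 of A2058, A375 and SKMEL-5 and at 0.0826, 0.805 and 0.223 CPM in replicate 2, all below the lowest hypoxic library (352 CPM).

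The response to hypoxia averaged over the 3 lines was tested first. It was led by CA9, a carbonic anhydrase of the cell surface that is a standard marker of low oxygen, which rose by 6.77 ± 1.18 (SE) on the log2 scale, 109-fold (log2 6.44 to 9.04 with 1 library left out at a time). NDRG1 rose by 4.13 ± 0.56, the iron carrier gene TF by 3.83 ± 0.49, the lipoprotein lipase inhibitor gene ANGPTL4 by 3.61 ± 0.50 and the vasodilator peptide gene ADM by 3.55 ± 0.49. VEGFA, the angiogenic growth factor, rose by 1.82 ± 0.26, 3.53-fold. Of the 26 tested genes of the mitochondrial genome 14 fell, among them MT-ND6 by 3.35 ± 0.36 and MT-ND2 by 3.07 ± 0.32 on the log2 scale. The other rises among the 10 largest were those of CACNA1B, a calcium channel subunit (6.40 ± 0.70), BEND5 (4.96 ± 0.55), NRN1 (4.85 ± 0.81), TMEM74B (4.73 ± 0.90) and ITGB4, a laminin-binding integrin subunit (4.66 ± 0.59). CACNA1B was at most 0.110 CPM and TMEM74B at most 0.169 CPM in the normoxic libraries, and BEND5 at most 0.154 CPM in those of A2058, close to the limit of 3 counts, so the sizes of these rises rest on few counts. EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, rose by 2.75 ± 0.48 (edgeR adjusted p = 0.0267), whereas HIF1A (0.48 ± 0.25, adjusted p = 0.320) and ARNT (0.61 ± 0.29, adjusted p = 0.283) did not pass the threshold; ARNT turned to -0.07 without the 3 hypoxic libraries that stood apart. CA9 (ENSG00000107159.13) lies on chromosome 9 from 35673856 to 35681159 in GRCh38, and averaged 544 ± 256, 641 ± 68.2 and 509 ± 223 CPM (SD, n = 2) in hypoxic A2058, A375 and SKMEL-5 against 9.53 ± 13.4, 2.86 ± 2.90 and 5.02 ± 6.78 CPM in normoxia.

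In edgeR's quasi-likelihood test over 6 hypoxic and 6 normoxic libraries, 192 genes rose and 28 fell in the 3-line mean at an adjusted p under 0.05. The test takes the libraries as independent. Differences between replicates 1 and 2 correlated across genes between A375 and SKMEL-5, at 0.80 in hypoxia and 0.58 in normoxia. Its standard errors and p-values may therefore be too small. In the mean of A2058 and A375 alone 34 genes rose and 14 fell, and in that of A2058 and SKMEL-5 24 and 10. All 192 risers and 27 of the 28 fallers moved in the same direction in each line. In 180 of the risers and 27 of the fallers the hypoxic and normoxic libraries did not overlap in any line. Of all 19636 tested genes 954 were separated upward and 547 downward in this way. The 220 called genes were selected on the same libraries, so their agreement between lines is partly set by that selection. The median riser was 3.81-fold higher, 189 of the 192 rose at least 2-fold, 89 at least 4-fold, and 172 were protein-coding. The 28 fallers were 14 genes of the mitochondrial genome (8 mRNAs and 6 tRNAs), 3 nuclear copies of mitochondrial genes and 11 other nuclear genes, among them SPHK1, a sphingosine kinase (-1.47 ± 0.22, adjusted p = 0.0133), and WWC1, a regulator of Hippo signalling (-1.51 ± 0.28, adjusted p = 0.0315). With the 3 hypoxic libraries that stood apart left out, 27 genes rose and 3 fell, 25 of them among the 220. Of the named genes BEND5, ITGB4, ANGPTL4, ADM, SLC2A3, P4HA2, FUT11, CDH13, MT-ND6 and MTND2P28 were still past the threshold. Leaving out 1 library at a time gave 9 risers (without A375 normoxia 2) to 823 (without A375 hypoxia 2) and 4 fallers (without A375 normoxia 1) to 297 (without A375 hypoxia 2), while DESeq2 called 1110 and 433 and limma-voom 153 and 25.

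**Figure D2:**
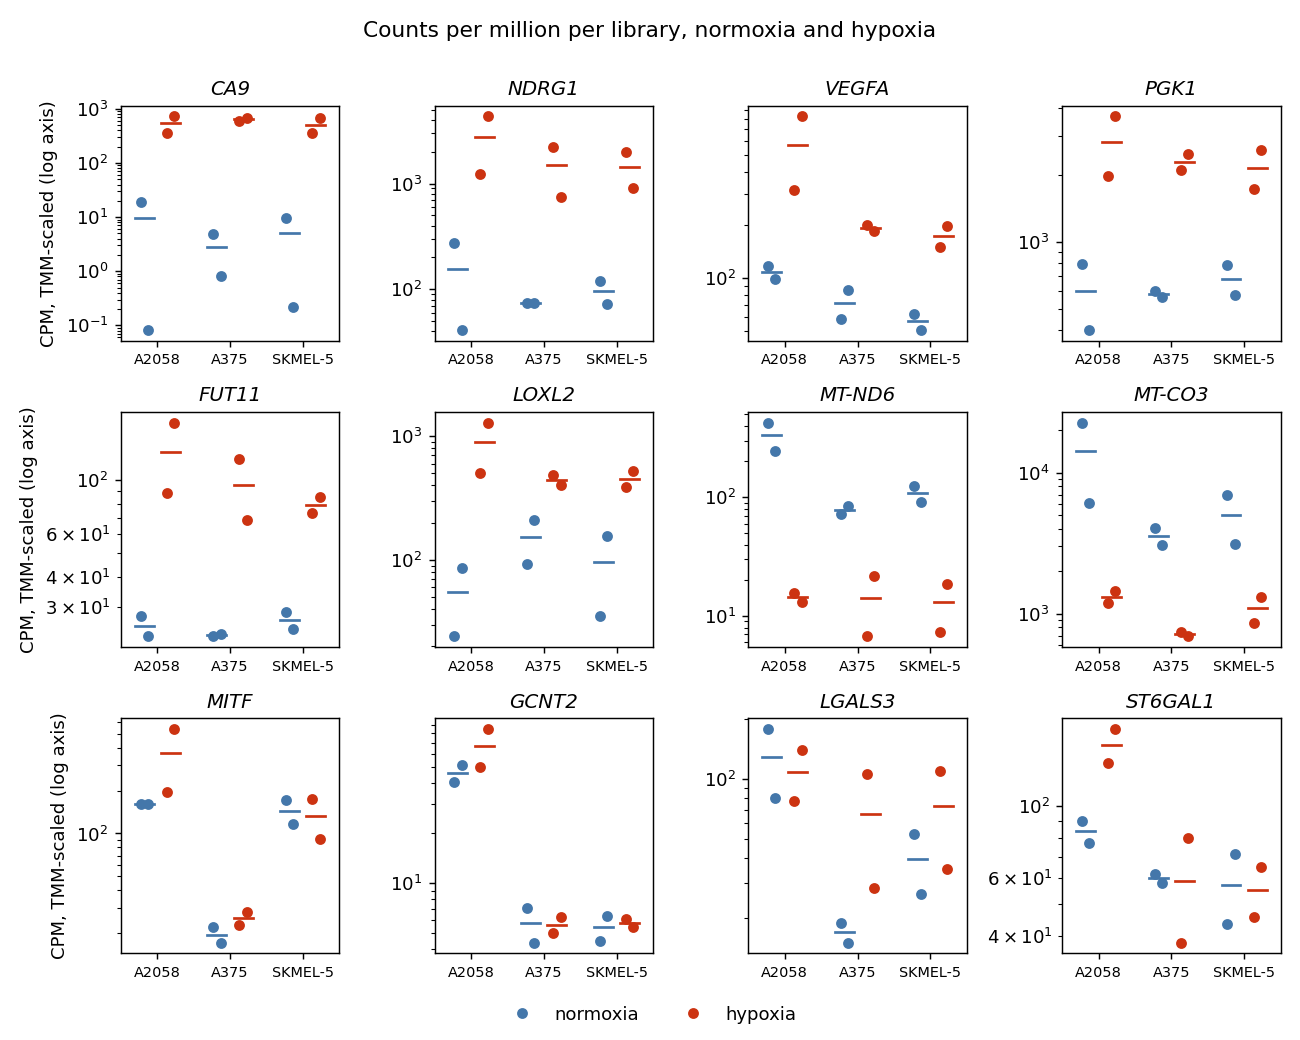
CPM (TMM-scaled, log axis) of 12 genes in each library, by cell line, with normoxia in blue and hypoxia in red; points are libraries and bars the mean of the 2 libraries. In all 3 lines the hypoxic libraries lie above the normoxic ones for CA9, NDRG1, VEGFA, PGK1, FUT11 and LOXL2 and below them for MT-ND6 and MT-CO3, and they overlap in at least 1 line for LGALS3, GCNT2, ST6GAL1 and MITF.

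Targets of the hypoxia-inducible factors rose together. Of 29 tested members of the hypoxia list, 23 rose, and 28 adjusted over the list alone, with a median of 2.18 on the log2 scale. LOX (0.96) was the member that did not pass. Part of the glycolysis and glucose transport list rose with them: 8 of 22 members, and 18 adjusted over the list alone, with a median of 1.33. Here the glucose transporter SLC2A3 rose by 2.53 ± 0.35 (adjusted p = 0.0113) and PGK1, which makes ATP in glycolysis, by 1.96 ± 0.28 (adjusted p = 0.0115). Camera gave an adjusted p of 1.22e-52 for the hypoxia list, which held at an adjusted p = 0.0481 with an estimated correlation, and 3.09e-25 for glycolysis, which did not (adjusted p = 0.0568 with an estimated correlation). Without the 3 hypoxic libraries that stood apart, 5 hypoxia genes and 1 glycolysis gene passed, 28 and 17 adjusted over the list alone, and the hypoxia list had an adjusted p = 0.149 with an estimated correlation. Within normoxia the hypoxia list averaged 5.14, 3.87 and 4.48 log2 CPM in replicate 1 of A2058, A375 and SKMEL-5 and 3.70, 3.70 and 3.70 in replicate 2, against 6.06 to 7.88 in the hypoxic libraries.

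The 13 mRNAs of the mitochondrial genome, which encode core subunits of the respiratory chain and ATP synthase, were lower in hypoxia. Of these, 8 fell, and all 13 adjusted over the list alone, with a median of -2.39 on the log2 scale. MT-ND6 (ENSG00000198695.2, chromosome M, 14149 to 14673 in GRCh38) averaged 335 CPM in normoxia and 14.4 in hypoxia in A2058, where libraries lay at 424 and 246 against 15.7 and 13.2. MT-CO3, a cytochrome oxidase subunit, fell by 2.65 ± 0.38 (adjusted p = 0.0115), and MT-CYB by 2.76 ± 0.35 (adjusted p = 0.00882). Camera gave the list an adjusted p of 1.17e-35, and it had an adjusted p = 0.0568 with an estimated correlation. Of 36 nuclear respiratory chain genes 0 passed, also adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.439) over lines that differed (0.06 in A2058, 0.30 in A375 and -0.53 in SKMEL-5) and ATP5MC1 at -1.12 ± 0.33 (adjusted p = 0.122). Of 20 TCA cycle genes 0 passed, and 1 adjusted over the list alone, SUCLG2, a succinate-CoA ligase subunit (1.30 ± 0.28, adjusted p = 0.0527), with a median of -0.06 (camera adjusted p = 0.484). Genes on the mitochondrial genome took 20.1 and 7.64% of counts in the A2058 normoxic libraries and 1.22 and 1.74% in the hypoxic ones, 4.13 and 2.97% against 3.32 and 0.648% in A375, and 6.31 and 2.79% against 3.13 and 1.35% in SKMEL-5. Of the 13, 1 passed without the 3 hypoxic libraries that stood apart, and 13 adjusted over the list alone. MTND2P28 (-3.06 ± 0.28) is a nuclear copy of MT-ND2, and the counting could have split reads between them; MT-ATP8 and MT-ATP6 overlap on the genome.

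Some genes of the extracellular matrix rose. Of 28 tested members of the collagen and matrix list 4 rose and 14 adjusted over the list alone, with a median of 0.87. They were LOXL2, which crosslinks collagen (2.60 ± 0.47, adjusted p = 0.0283), P4HA2, a collagen prolyl hydroxylase subunit (2.32 ± 0.25, adjusted p = 0.00460), the collagen lysyl hydroxylase gene PLOD1 (1.94) and the gelatinase gene MMP2 (1.34). Camera gave an adjusted p of 5.80e-14, and the list had an adjusted p = 0.0568 with an estimated correlation. When the 3 hypoxic libraries that stood apart were left out, 2 members passed, and 9 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). Fibroblast markers had a median of 0.67 (camera adjusted p = 0.0935). Over all 7 tested markers the median was 0.46, and 0.89 without those libraries. The camera adjusted p was then 0.00119, and 0.149 with an estimated correlation. CDH13, a cadherin anchored to the membrane by a lipid, rose by 1.69 ± 0.17 (adjusted p = 0.00460).

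Among genes that act on sugars, few passed the threshold over all genes. FUT11, of the fucosyltransferase family, rose 4.01-fold (SE 0.23 on the log2 scale, adjusted p = 0.00560), from 25.1 ± 3.38, 23.0 ± 0.290 and 26.4 ± 3.01 CPM (SD, n = 2) in normoxic A2058, A375 and SKMEL-5 to 130 ± 59.5, 95.2 ± 37.6 and 79.1 ± 8.54 in hypoxia. It lies on chromosome 10 from 73772291 to 73780251 (ENSG00000196968.11, GRCh38). Of the 14 tested members of the fucosylation list it was the 1 that rose, also adjusted over the list alone, with a list median of 0.09 (camera adjusted p = 0.337). GBE1, the glycogen branching enzyme (2.14 ± 0.30, adjusted p = 0.0114; ENSG00000114480.13, chromosome 3, 81489699 to 81762161), and MPI, which links fructose and mannose phosphates (1.54 ± 0.30, adjusted p = 0.0406; ENSG00000178802.18, chromosome 15, 74890005 to 74902219), were the 2 of 25 members of the hexosamine and nucleotide sugar list that rose, 3 adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0678). Of 17 proteoglycan core proteins 2 rose, the heparan sulphate carriers AGRN (1.62 ± 0.33, adjusted p = 0.0463; ENSG00000188157.15, chromosome 1, 1020123 to 1056118) and GPC6 (1.60 ± 0.33, adjusted p = 0.0496; ENSG00000183098.11, chromosome 13, 93226842 to 94407401), and 6 adjusted over the list alone, with a median of 0.80. Camera gave the proteoglycan list an adjusted p of 3.81e-05, and it had an adjusted p = 0.0704 with an estimated correlation. Without the 3 hypoxic libraries that stood apart, FUT11 was the only member of the 12 sugar lists past the threshold; AGRN and GPC6 were also lost with DESeq2's size factors.

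The other 9 sugar lists had 0 members past the threshold over all genes in edgeR's test. Glycosphingolipid genes were the nearest, with 6 of 18 higher and 1 lower (GLA) adjusted over the list alone, a median of 0.69 and a camera adjusted p of 0.00862 (adjusted p = 0.0990 with an estimated correlation). HEXA, a lysosomal hexosaminidase subunit of this list, stood at 0.96 ± 0.23 (adjusted p = 0.0740). Among galectins, which bind galactosides, LGALS1 (0.82 ± 0.27, adjusted p = 0.153) and LGALS8 (0.79 ± 0.18, adjusted p = 0.0682) were the 2 of 6 higher adjusted over the list alone, with LGALS3 at 0.87 ± 0.40 (adjusted p = 0.273), a median of 0.79 and a camera adjusted p of 0.0425 (adjusted p = 0.182 with an estimated correlation). LGALS3 turned to -0.07 without the 3 hypoxic libraries that stood apart. In the list for poly-LacNAc chains 2 of 10 were higher adjusted over the list alone, B3GNT4 (1.71 ± 0.44, adjusted p = 0.0867) and B3GNT7, with a median of 0.33 and a camera adjusted p of 0.0311 (adjusted p = 0.159 with an estimated correlation). GCNT2, which adds branches to these chains, stood at 0.20 ± 0.23 (adjusted p = 0.660). Of 17 sialyltransferases 1 was lower adjusted over the list alone, ST8SIA1, the ganglioside GD3 synthase (-1.30 ± 0.31, adjusted p = 0.0740), and the list median was 0.28 (camera adjusted p = 0.716); ST3GAL1 stood at 0.68 ± 0.33 (adjusted p = 0.287) and ST6GAL1 at 0.27 ± 0.24 (adjusted p = 0.548).

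Of the remaining sugar lists, N-glycan processing had 0 of 14 past the threshold adjusted over the list alone and a median of 0.20 (camera adjusted p = 0.403). Its mannosidase MAN1B1 stood at 0.73 ± 0.20 (adjusted p = 0.102), the branching enzyme MGAT5 at 0.39 ± 0.41 (adjusted p = 0.629) and the core fucosyltransferase FUT8 at -0.05 ± 0.37 (adjusted p = 0.980), which turned to 0.48 without the 3 hypoxic libraries that stood apart. Sialic acid metabolism had 0 of 11 adjusted over the list alone and a median of 0.18 (camera adjusted p = 0.545), with the sialic acid esterase gene SIAE at 0.84 ± 0.28 (adjusted p = 0.152). O-GalNAc glycosylation had 1 of 17 higher adjusted over the list alone, C1GALT1, the core 1 synthase (1.08 ± 0.24, adjusted p = 0.0611), and a median of 0.11 (camera adjusted p = 0.239). Glycosaminoglycan synthesis had 1 of 40, the chondroitin polymerising factor CHPF (1.09 ± 0.24, adjusted p = 0.0553), and a median of 0.19 (camera adjusted p = 0.716). The dolichol pathway and oligosaccharyltransferase list had 2 of 27, GANAB and TUSC3 (0.80 ± 0.19, adjusted p = 0.0695), and a median of 0.19 (camera adjusted p = 0.0953). Over all tested members, as used where libraries are left out, medians were 0.18 for glycosaminoglycan synthesis and 0.19 for the dolichol pathway. They were 0.12 for O-GalNAc glycosylation and 0.26 for N-glycan processing. Several of these lists gained a camera call when the 3 hypoxic libraries that stood apart were left out. The adjusted p became 0.000198 for glycosaminoglycan synthesis (median 0.34), 0.00262 for the dolichol pathway (0.22), 0.00460 for O-GalNAc glycosylation (0.37) and 0.0397 for N-glycan processing (0.25). With an estimated correlation these were 0.361, 0.361, 0.325 and 0.411. Poly-LacNAc extension (adjusted p = 0.106) and galectins (0.326) lost theirs. Over all genes 3723 had an unadjusted p under 0.05 in the 3-line mean, and DESeq2 called LGALS1, LGALS8, B3GNT4, HEXA, ST8SIA1, MAN1B1, C1GALT1, CHPF and TUSC3 in the same directions. These were part of 1110 rises and 433 falls called by DESeq2. Among named genes of other lists it also called DDIT3, HLA-C, SUCLG2, DHCR7, FAP, ATP5MC1 and GPNMB, which edgeR did not.

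**Figure D3:**
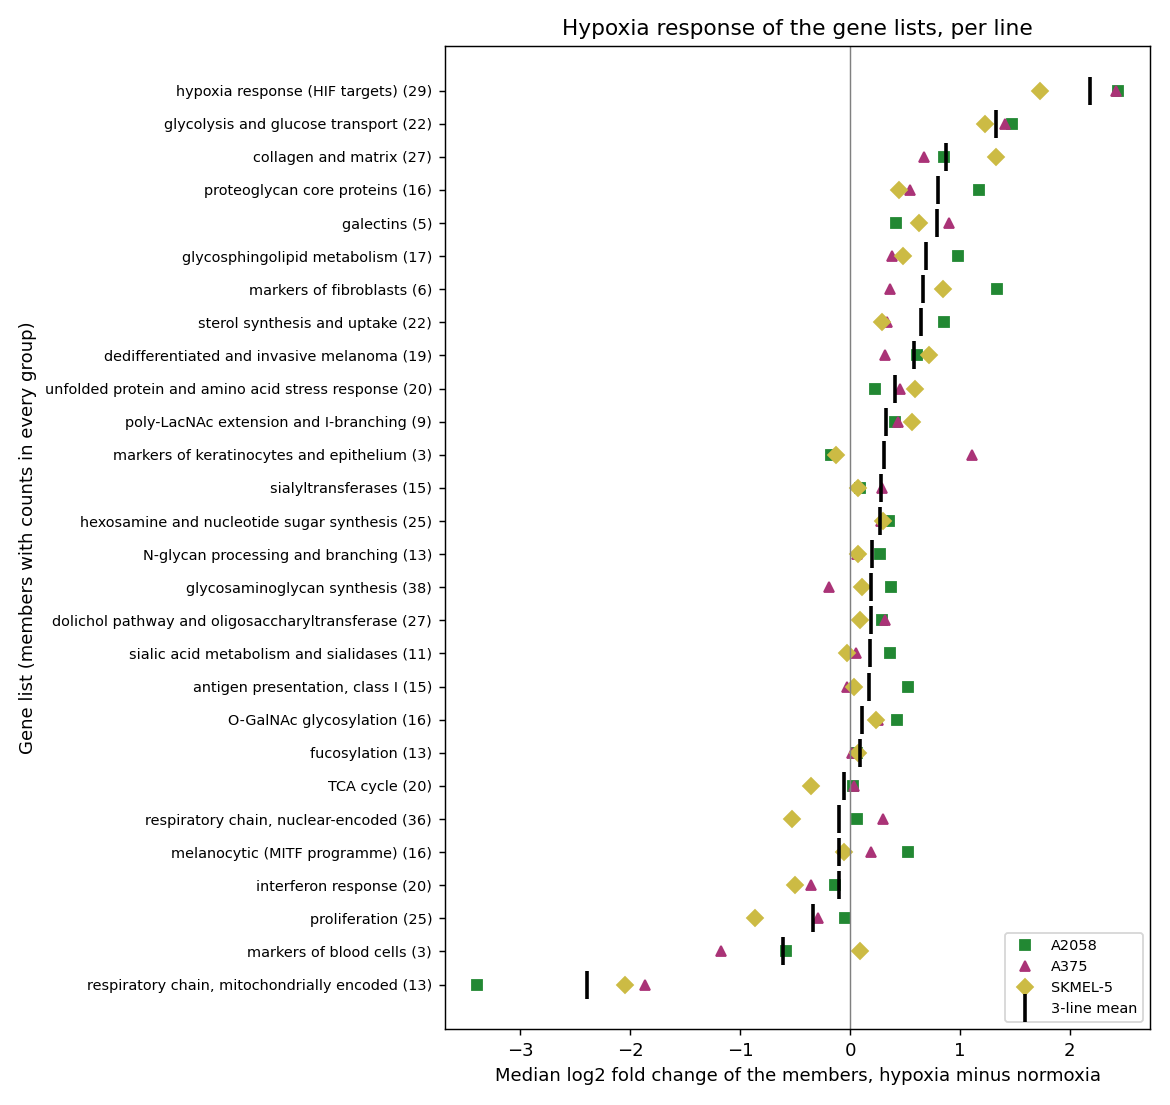
Median log2 fold change (hypoxia minus normoxia) of the members of each of the 28 gene lists, with the number of members with counts in every group in brackets; symbols are the 3 lines and black bars the 3-line mean. The hypoxia list (2.18) and glycolysis (1.33) have the highest 3-line medians and the mitochondrially encoded respiratory chain (-2.39) the lowest.

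In the dedifferentiated and invasive melanoma list AXL, a receptor tyrosine kinase of that state, stood at 0.58 ± 0.45 (adjusted p = 0.495), and the list had a median of 0.58 and a camera adjusted p of 0.0256 (adjusted p = 0.556 with an estimated correlation). Of 20 melanocytic genes 0 passed, also adjusted over the list alone, with MITF, the regulator of that programme, at 0.49 ± 0.28 (adjusted p = 0.360) and GPNMB at 1.24 ± 0.38 (adjusted p = 0.135). The median of the 16 melanocytic genes with counts in every group was -0.10, the mean of all 20 was 0.17 and camera's direction was up (adjusted p = 0.713). Of 25 proliferation genes 0 passed, also adjusted over the list alone, with AURKA at -0.63 ± 0.28 (adjusted p = 0.258), a median of -0.34 and a camera adjusted p of 0.00696 downward (adjusted p = 0.624 with an estimated correlation). In the 3 hypoxic libraries that stood apart these genes differed from the other hypoxic library by medians of 0.28, -0.91 and -1.32 in A2058, A375 and SKMEL-5, and without those libraries the camera adjusted p was 0.264.

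Sterol synthesis and uptake had 0 of 22 members past the threshold and 7 higher adjusted over the list alone, with DHCR7, the last enzyme of cholesterol synthesis, at 1.17 ± 0.26 (adjusted p = 0.0572), a median of 0.64 and a camera adjusted p of 0.000114 (adjusted p = 0.231 with an estimated correlation). None (0) was higher adjusted over the list alone without the 3 hypoxic libraries that stood apart. The unfolded protein and amino acid stress list had 0 of 20, and 6 higher and 1 lower (SDF2L1) adjusted over the list alone, with the stress factor DDIT3 4.59-fold higher (SE 0.51 on the log2 scale, adjusted p = 0.0690; log2 1.55 to 2.47 with 1 library left out), a median of 0.41 and a camera adjusted p of 0.0256 (adjusted p = 0.409 with an estimated correlation). DDIT3 stood at log2 0.46 ± 0.86 in A2058 against 3.22 ± 0.93 in A375 and 2.92 ± 0.91 in SKMEL-5, where the SD of the hypoxic libraries (112 and 116 CPM, n = 2) was as large as their mean (106 and 110 CPM). Interferon response had 0 of 20, also adjusted over the list alone, with MX2 at -0.60 ± 0.24 (adjusted p = 0.223) and a median of -0.10 (camera adjusted p = 0.484). Class I antigen presentation had 0 of 15 over all genes and 3 higher adjusted over the list alone, with a list median of 0.18 (camera adjusted p = 0.325). HLA-C, which can share reads with its paralogs, stood at 1.42 ± 0.31 (adjusted p = 0.0595). Markers of other cell types gave 0 members past the threshold over all genes. Adjusted over the list alone, 2 of 7 fibroblast markers were higher, FAP (1.56 ± 0.47, adjusted p = 0.130) and PDGFRA, with a median of 0.67 (camera adjusted p = 0.0935). Of 3 keratinocyte and epithelial markers 1 was, DSP (1.05 ± 0.35, adjusted p = 0.158), with a median of 0.31 (camera adjusted p = 0.302), and of 4 blood cell markers 0, with CD14 at -1.21 ± 0.58 (adjusted p = 0.287) and a median of -0.61 (camera adjusted p = 0.468).

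The second question was what each line did on its own. In A2058, CDH13 rose 9.84-fold, from 3.22 ± 0.274 to 31.7 ± 1.16 CPM (SD, n = 2; log2 3.30 ± 0.31 SE, adjusted p = 0.00825), and the pseudogene MTND2P28 fell by 4.17 ± 0.51 on the log2 scale (adjusted p = 0.0489; log2 change -4.70 to -3.31 with 1 library left out). CDH13 (ENSG00000140945.17) lies on chromosome 16 from 82626803 to 83800640 and MTND2P28 (ENSG00000225630.1) on chromosome 1 from 629640 to 630683. These were the 1 riser and 1 faller of edgeR's test in A2058, with 1798 genes at an unadjusted p under 0.05 where 982 were expected. Adjusted over the list alone, A2058 had 26 of 29 hypoxia genes, 15 of 22 glycolysis genes, 7 of 22 sterol genes and 6 of 28 matrix genes higher and 13 of 13 mitochondrial mRNAs lower. DESeq2 called 236 genes higher and 121 lower and limma-voom 6 and 4. Both calls were lost without the 3 hypoxic libraries that stood apart, and without A2058 normoxia 1 or A2058 hypoxia 2 alone; CDH13 was also lost without A2058 normoxia 2, and MTND2P28 without A2058 hypoxia 1 or any 1 of the A375 or SKMEL-5 normoxic libraries.

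In A375, CA9 stood at a log2 change of 7.80 ± 2.13 and CACNA1B at 8.46 ± 1.27, and in SKMEL-5 at 6.67 ± 2.03 and 8.93 ± 1.31, but edgeR's test called 0 genes in either direction in both lines, with smallest adjusted p-values of 0.683 and 0.178. There were 1100 and 1283 genes at an unadjusted p under 0.05 against 982 expected. DESeq2 called 94 higher and 13 lower in A375 and 95 and 25 in SKMEL-5, and limma-voom 0 in both. Adjusted over the list alone, 24 and 21 of 29 hypoxia genes and 15 and 7 of 22 glycolysis genes were higher in A375 and SKMEL-5, and 7 and 8 of 13 mitochondrial mRNAs lower. FUT11 was higher adjusted over its list alone in all 3 lines (log2 2.38 ± 0.41, 2.05 ± 0.41 and 1.58 ± 0.40 in A2058, A375 and SKMEL-5). On simulated data with the observed spread, the A375 comparison recovered 0% of 2-fold, 24% of 4-fold, 60% of 8-fold and 96% of 16-fold changes over 19636 genes. The 3-line mean recovered 18, 92, 100 and 100%. The simulation drew genes and libraries independently, without the shifts shared across genes in the hypoxic libraries that stood apart. These shares therefore need not hold for the real libraries. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.33. Because of the 0 calls in A375 and SKMEL-5, 0 genes rose or fell in each of the 3 lines in edgeR's test and by limma-voom, while DESeq2 called 21 higher and 8 lower in all 3.

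The third question was whether the lines responded differently. CDH13 had the smallest p (0.000116), with log2 changes of 3.30 ± 0.31 in A2058, 0.88 ± 0.29 in A375 and 0.88 ± 0.29 in SKMEL-5. NDUFA4L2, a hypoxia-induced relative of a respiratory chain subunit, stood at 7.40 ± 1.10, 0.84 ± 0.85 and 1.74 ± 0.87. The small GTPase gene ARL10 stood at 3.02 ± 0.47, 0.00 ± 0.54 and -0.48 ± 0.55, with at most 0.283 CPM in A375 and SKMEL-5, too little to judge a response there. The cell adhesion gene IGSF9 stood at 5.78 ± 1.02 (with at most 0.333 CPM in normoxic A2058), 0.38 ± 0.81 and 0.91 ± 0.82, and RGS5, a regulator of G protein signalling, at 3.16 ± 0.65, -0.09 ± 0.65 and -0.93 ± 0.63. CACNA1B stood at 1.82 ± 1.14 (with at most 0.632 CPM in A2058), 8.46 ± 1.27 and 8.93 ± 1.31. The pigment enzyme gene DCT stood at 0.96 ± 0.77, 1.77 ± 0.89 and -3.47 ± 0.93, where its level in A375 and SKMEL-5 was at most 2.64 CPM. Each of these had an adjusted p of 1 in edgeR's test of the difference, which called 0 genes, with 315 at an unadjusted p under 0.05 where 982 were expected. A count that far under the expected number means that the p-values of edgeR's test may be too large. Its 0 calls therefore do not show that the lines responded alike. DESeq2's likelihood ratio test called 8 and limma-voom 0. Across the 19636 genes, whose responses are not independent, the log2 changes of A375 and SKMEL-5 correlated at r = 0.602, those of A2058 and A375 at 0.365 and those of A2058 and SKMEL-5 at 0.334, and 71.1, 63.8 and 63.1% of genes had the same sign. The deviations of the hypoxic libraries that stood apart correlated in the same order, at 0.797, 0.469 and 0.409. Shifts shared by those libraries enter these responses, so the order cannot be read as likeness of the oxygen response alone.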

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

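The comparison with libraries regrouped line by line and the test of clock genes were set before their results were seen; the regrouping of A375 and SKMEL-5 together and the tests on line likeness, transcript length, GC content and mitochondrial transcripts were chosen after the patterns had been seen.

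Of 100 regroupings, drawn from the 108 distinct ways to split the libraries within lines, 1 gave 220 called genes in the 3-line mean. This was the real one, and the others gave at most 8. Splits that mix hypoxic and normoxic libraries move any oxygen effect into the spread, so this gap does not measure its strength. A share of 1 in 100 lies under the 5% set for this test. It argues against chance for that count if the 3 lines are independent, which the likeness of A375 and SKMEL-5 makes doubtful. If A375 and SKMEL-5 libraries of the same condition and number are moved together, 18 distinct splits exist, of which 1, the real one, gave as many (at most 8 in the others). Its share of 5.56% is the smallest that 18 splits allow and lies above the 5% set for this test, so chance stays open in that case.

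A few genes moved in opposite directions in different lines, with the hypoxic and normoxic libraries separated in each. By chance 16.7% of genes would be separated in a given direction in 1 line. These genes were also named for a small p for a difference between lines, so their separation is no support for one. SH3D21 responded by -1.68 ± 0.78 (SE) in A2058 against 3.15 ± 0.80 in A375, a difference of -4.84 on the log2 scale, and against 3.53 ± 0.82 in SKMEL-5, a difference of -5.22. EGLN3, a HIF prolyl hydroxylase gene, responded by 3.44 ± 0.69 in A2058 and -0.54 ± 0.73 in A375, a difference of 3.98, with at most 0.261 CPM in the A375 libraries. CELF2, a splicing factor gene, responded by 0.50 ± 0.48 in A2058 and -4.07 ± 0.82 in SKMEL-5, a difference of 4.57, with at most 0.486 CPM in the SKMEL-5 libraries. None of these differences passed edgeR's test of a pairwise difference above 1 or its test over the 3 lines (adjusted p = 1 for each).

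The A375 and SKMEL-5 libraries resemble each other more than 2 unrelated lines would be thought to. At 10 CPM or more in all 4 libraries of a line and under 0.5 CPM in all 4 of another, 0 genes separated A375 from SKMEL-5 against 117 between A2058 and SKMEL-5 and 119 between A2058 and A375, so the counts are consistent with cells of 1 origin under both names. MLANA, for which SKMEL-5 is widely used as a positive line, had 0 counts there, while MITF averaged 22.5 CPM in A375 (18.0 to 28.5 over 4 libraries) and 141 in SKMEL-5 (93.8 to 184). A375 RNA making up most of the SKMEL-5 libraries is argued against by 5 genes at 1 CPM or more in every A375 library and under 10% of that in SKMEL-5. Exchanging libraries of the same condition and number gave at most 0 such genes, but that comparison was chosen after all 34 other groupings of the 8 libraries, which also mix conditions, had been tried and had given up to 26. Separate lines in a like state cannot be told apart from 1 origin with 2 genes called different, because the counts hold no genotypes.

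In each line 1 hypoxic library stood apart, and the deviations correlated across genes at 0.469 (A2058 and A375), 0.409 (A2058 and SKMEL-5) and 0.797 (A375 and SKMEL-5). A transcript length bias (largest absolute Spearman rho 0.173 over the 3 lines) and a GC bias (0.204) stayed under the 0.3 they would have needed. Another hour or medium state at harvest may have contributed: the median deviation of 5 clock output genes was 0.620, 2.05 and 1.40 in A2058, A375 and SKMEL-5, which lies above 1 in A375 and SKMEL-5 only and leaves it open. TXNIP, which follows glucose, was higher by 1.89, 4.07 and 4.26 in the same libraries. The labels give no harvest time or batch, and no biological explanation was tested.

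The median of the mitochondrially encoded mRNAs fell in hypoxia in all 3 lines. With library sizes made of nuclear genes the median of the 13 mRNAs was -2.38, so they fell relative to nuclear genes. This cannot decide on scaling by the mitochondrial share. TMM already rests on most genes, of which 26 of 19636 are mitochondrial, so a value near the -2.39 of the main analysis was set in advance. A loss of long transcripts in the normoxic replicate 1 libraries is argued against, since the median was -1.93 without them. Fewer mitochondria or genome copies could not be decided: the change of the mitochondrial ribosomal RNAs as a share of the mRNA change was 0.744, -0.870 and -0.296 in A2058, A375 and SKMEL-5 with all libraries, and 0.877, 0.783 and 0.692 without the 3 libraries that stood apart. Lower transcription of the mitochondrial genome in hypoxia is the biological alternative that the design offers, and it was not tested.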

How the results depend on the processing

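Leaving out the 3 hypoxic libraries that stood apart, the blocks other than the one within lines, the 2-line means, the length trend and the removal of mitochondrial genes were chosen after the data had been seen. The 192 rises and 28 falls of the 3-line mean became 1365 and 490 without the low-count filter, 1110 and 433 with DESeq2, and 425 and 71 in the additive model. Without the filter the calls were 303 and 94 in A2058, 358 and 26 in A375, 311 and 39 in SKMEL-5, 69 and 12 in all 3 lines, and 83 for a difference between lines. There 37389 genes were tested in place of 19636 and the prior degrees of freedom became infinite in place of 5.02, so that the spread of single genes no longer counted; 1809 of the 1855 genes called passed the filter. DESeq2 called 236 and 121 in A2058, 94 and 13 in A375, 95 and 25 in SKMEL-5, 21 and 8 in all 3 lines, and 8 for a difference; of the 220 genes it also called 216. Limma-voom called 6 and 4 in A2058. With fry in place of camera 3 lists lost their call, the unfolded protein response (adjusted p = 0.0789), proliferation (0.349) and dedifferentiated melanoma (0.244). Another 3 gained one, fucosylation (0.0281), hexosamine and nucleotide sugars (0.0141) and keratinocyte markers (0.0333). The A2058 counts were 0 and 0 with its 4 libraries alone, where SKMEL-5 alone gave 2 rises, and the fall was lost with the stricter filter (0); with the length trend removed 2 fell. Without the 3 hypoxic libraries that stood apart, 5 lists gained a camera call (N-glycan processing, O-GalNAc glycosylation, glycosaminoglycan synthesis, dolichol pathway and fibroblast markers), none of them past the threshold with an estimated correlation (adjusted p = 0.149 for fibroblast markers), and 3 lost it (proliferation, poly-LacNAc extension and galectins). The 3-line mean then gave 27 and 3, A2058 gave 0 and 0, and LGALS3 turned to -0.0741, ARNT to -0.0670, FUT8 to 0.48 and the camera direction of class I antigen presentation to down (median 0.0382). With mitochondrial genes left out 11 fell; 14 of the 28 were not tested there, and what ended the other calls was not examined. Except where a cause is named, the cause was not tested. The additive model turned DCT to 0.0367.

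In the mean of A2058 and A375 alone 34 genes rose and 14 fell, and FUT8 turned to 0.0549, DCT to 1.36, the TCA cycle list to 0.12 and the nuclear respiratory chain list to 0.14. In that of A2058 and SKMEL-5 the counts were 24 and 10 and FUT8 turned to 0.10. In that of A375 and SKMEL-5 they were 6 and 1, and EGLN3 turned to -0.17, ARL10 to -0.24, RGS5 to -0.51 and ST6GAL1 to -0.0346, with the camera direction down for melanocytic genes (median -0.0728), N-glycan processing (median 0.0544) and glycosaminoglycan synthesis (-0.0401). Leaving out 1 library, where the other library of its group is assumed to vary like the other groups, gave 9 to 823 rises and 4 to 297 falls in the 3-line mean, 0 to 12 and 0 to 2 in A2058, 0 to 8 rises in A375 and 0 to 1 in SKMEL-5. Rises and falls were 86 and 18 without A2058 normoxia 1, 77 and 17 without A2058 normoxia 2, 284 and 59 without A2058 hypoxia 1, 52 and 11 without A2058 hypoxia 2, 11 and 4 without A375 normoxia 1, 9 and 6 without A375 normoxia 2, 127 and 20 without A375 hypoxia 1, 823 and 297 without A375 hypoxia 2, 33 and 9 without SKMEL-5 normoxia 1, 15 and 10 without SKMEL-5 normoxia 2, and 92 and 14 without SKMEL-5 hypoxia 1. The results whose sign or camera direction changed there ranged from -0.19 to 0.10 (nuclear respiratory chain), -0.0696 to 0.28 (glycosaminoglycan synthesis), -0.14 to 0.0594 (TCA cycle), -0.30 to 0.10 (interferon response), -0.11 to 0.34 (melanocytic), -0.45 to 0.16 (FUT8), -0.98 to 0.0175 (DCT) and -0.0466 to 0.68 (MGAT5). The medians of O-GalNAc glycosylation (-0.13 to 0.49) and fucosylation (-0.12 to 0.30) also changed sign. Ranges of lists are of medians over all tested members, which for melanocytic genes was 0.06 with all libraries. The 3-line fold changes of 8 called named genes moved by more than 1.5 times there, with log2 ranges of 6.44 to 9.04 (CA9), 5.64 to 7.75 (CACNA1B), 4.27 to 5.61 (NRN1), 3.77 to 6.20 (TMEM74B), 3.91 to 4.94 (ITGB4), 3.76 to 4.78 (NDRG1), 3.55 to 4.55 (TF) and 2.11 to 3.02 (EPAS1). So did MTND2P28 in A2058 (-4.70 to -3.31). Among genes not called, so did DCT, DDIT3 (1.55 to 2.47), AXL (0.31 to 1.23), CD14 (-2.04 to -0.94), IGSF9 (1.70 to 2.80) and SH3D21 (0.97 to 1.94). The called named genes kept their direction under every alternative that tested them, which leaves out the mitochondrial genes where those were removed. The counts with DESeq2's size factors or a minimum log2 change of 1 stayed within 1.5 times. Depth limits little here: 3 counts were 0.0553 to 0.0887 CPM, and the spread between replicates was far larger.

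The labels do not say whether the replicate numbers pair the libraries. Same-numbered normoxic and hypoxic libraries deviated together with a correlation across genes of -0.30 in A2058, 0.23 in A375 and 0.26 in SKMEL-5. Between A375 and SKMEL-5 the pairing by number gave 0.80 in hypoxia and 0.58 in normoxia, and A2058 normoxia gave 0.26 and 0.47 with their normoxic libraries, but A2058 hypoxia gave -0.47 and -0.41 with their hypoxic ones. With a replicate block within each line 78 genes rose and 13 fell in the 3-line mean, 76 of these 91 among the 220, and 0 and 0 in A2058. Of the 88 results on single genes 15 lost their call with this block, and of the 28 lists 3 did. With a replicate block shared by the lines 309 rose and 48 fell, with 0 falls in A2058. With the A2058 numbers crossed, the block gave 477 and 132 in the 3-line mean, 9 and 3 in A2058, 1 rise in A375 and 1 gene for a difference between lines.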

Other observations

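The genes and values in this part were chosen after the data had been seen. They were picked from the called genes, and no list of their families was written down or tested, so they say nothing on the other members. The histone demethylase genes KDM3A (1.53 ± 0.29 SE on the log2 scale, edgeR adjusted p = 0.0329), KDM4B (1.29 ± 0.21, adjusted p = 0.0202), KDM5B (1.34 ± 0.27, adjusted p = 0.0428) and KDM7A (1.54 ± 0.30, adjusted p = 0.0368) rose 2.89-, 2.44-, 2.54- and 2.91-fold. TET1, which oxidises methylcytosine, rose 4.11-fold (adjusted p = 0.0222). Of the genes for IGF-binding proteins, IGFBP3 rose 6.25-fold (adjusted p = 0.00541), IGFBP5 6.52-fold (adjusted p = 0.0110) and IGFBP6 2.58-fold (adjusted p = 0.0331).

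Some single genes that handle lipids were picked in the same way, while the list on sterol synthesis and uptake had 0 of 22 members past the threshold. SCD, which makes monounsaturated fatty acids, rose 4.97-fold (adjusted p = 0.0218), SREBF2, the regulator of sterol genes, 3.55-fold (adjusted p = 0.0434), and the cholesterol exporter gene ABCG1 4.26-fold (adjusted p = 0.0406), the last with libraries separated in 2 lines. VLDLR, a lipoprotein receptor gene (4.54-fold, adjusted p = 0.0120), and HILPDA, a lipid droplet gene (7.89-fold, adjusted p = 0.0329), are members of the hypoxia list. Without the 3 hypoxic libraries that stood apart, IGFBP3 and VLDLR were the genes of these 2 paragraphs still past the threshold.

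The lines differed in pigment cell genes. PMEL averaged 1026 CPM in A2058 (351 to 2454 over 4 libraries), 0.811 in A375 and 0.638 in SKMEL-5, and DCT 1122, 0.619 and 1.17 CPM. AXL averaged 240, 587 and 439 CPM. In normoxia, replicate 1 minus replicate 2 correlated with transcript length across 9493 genes at a Spearman rho of -0.515 in A2058, -0.0201 in A375 and -0.514 in SKMEL-5.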
